A study of Caenorhabditis elegans with 12 samples.

How the data were processed

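PAT-seq reads the 3' ends of polyadenylated RNA together with the length of the poly(A) tail. Per the labels, the 12 samples were early embryos of which over 90% were between the zygote and the 24-cell stage. Libraries began from 1 µg of RNA, the ends of poly(A) tails were extended with a tag by Klenow polymerase, RNA was fragmented with RNase T1, and fragments in a window of 120 to 300 bases were sequenced directionally without depletion of ribosomal RNA. The labels repeat both feeding protocols for all samples. They describe OP50 bacteria for N2 and, for RNAi, HT115(DE3) bacteria induced for 6 h with IPTG.

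The authors deposited read counts per gene and per poly(A) peak, and mean tail lengths in nt per gene and per peak. The deposited counts are whole numbers with no normalization. The deposited tail lengths in nt are means over the reads with a measured tail, with no value where none was estimated. How the tails were computed and the minimum number of reads behind a value are not given in the sources used here, but no value stands where the count of the gene is under 10. The deposited positions of genes and peaks, in bp, are on ce10. The submitters' notes list Bowtie2 2.2.2, and the annotation in the gene table is the UCSC RefSeq set for ce10, while the peaks were called by nesoni with settings not given in the sources used here. The reference copy at hand is on WBcel235, so only its gene symbols were used and no coordinates were moved between builds. Of 43347 names in the gene table, 42780 (98.7%) matched it.

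Of 31753 gene features, 16678 held 1 coding gene. Another 318 merged more than 1 coding gene and held 6.06% to 9.39% of the reads of a library; they stayed in the fits but were not used to name genes. Gene reads per library ranged from 4613974 to 10229871, and from 2282120 to 5294608 without rRNA. Reads are not independent molecules, since no molecular identifiers are described in the sources used here, and replicates differed by more than counting error (chi-square per degree of freedom of 8.33 to 22.8 within groups).

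Samples were grouped by title into 6 groups of 2. The comparisons, tests, alternatives, gene lists and naming rule were fixed before the data were examined. They comprised 5 comparisons with N2 and 4 between other groups. Expression was tested in R 4.3.3 with edgeR 4.0.16, by quasi-likelihood F tests on all 12 libraries with 1 coefficient per group, filterByExpr and TMM factors, for 9403 genes. Mean tails in nt, neither logged nor centred, were tested with limma 3.58.1, with a variance trend on log2 mean reads. The test covered 5471 genes with a value in all 12 libraries and at least 10 reads. The reads in this filter, in the trend and in the weights were all reads of the gene. The number with a measured tail is not given in the sources used here, so weights by reads need not follow the precision of a mean tail. Poly(A) site choice was tested with edgeR's diffSpliceDGE in genes with more than 1 peak. All p-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. Tests were two-sided. Log2 CPM used a prior count of 2, except that means of the yolk and sperm lists were taken over log2 (CPM + 0.5), and SE values are those of the fitted coefficients.

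The 16 gene lists were study genes, maternal cell fate regulators, maternal RNA-binding proteins, poly(A) machinery, endomesoderm and gut genes, anterior and ectoderm genes, muscle and posterior genes, oocyte and eggshell genes, yolk and adult intestine genes, sperm genes, late embryo and larval tissue genes, ribosomal protein genes, histone genes, vitamin B12 and propionate genes, RNAi machinery and stress genes. Each was tested with camera at a preset correlation of 0.01 and at an estimated correlation, adjusted over the lists of a comparison, and its members were counted over all genes tested and over the list alone.

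Genes were named by a rule. It admitted the 6 study genes, up to 8 called genes with the largest rise and 8 with the largest fall whose libraries did not overlap between the groups, and up to 4 members of each list with the smallest p. Genes with only a sequence name were left out where others served. Genes outside the rule are gap-2, cdc-14, D1014.2 and E01G4.5 for site choice, where few passed, and the genes of the weighed patterns, which were chosen after their values were seen.

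Changes that 2 groups share against N2 were set beside 40 pairs of unchanged groups that shared the same N2 libraries, built from the differences between replicates. Calls shared by chance were counted in 40 draws of 12 unchanged libraries, normal for centred tails and negative binomial for counts. Alternatives were DESeq2 1.42.0, RLE factors, no low-count filter, the 4 samples of a comparison alone, a replicate block, each library left out in turn, at least 50 reads per tail value, weights by reads, centring on library medians, log2 tails, peaks with a mean of at least 20 reads, and the neg-1 peak in place of its gene. Alternatives chosen after seeing the data were rRNA features left out, mex-6(pk440) as the control, tails centred and scaled, gene lists on centred tails, a limma test of log-ratios for site choice, and a linear model on the library medians of tail length.

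The tests were tested on simulated data, made from the deposited values with known changes planted in 2 libraries. For site choice the spread among the peaks of a gene was set by hand and not taken from the deposited values. At a log2 change of 1, edgeR found 24 of 100 changed genes, and at 2 it found 81 of 100, with 2 false calls among 107. DESeq2 found 23 and 76. Limma found 23 of 100 tails changed by 10 nt and 77 of 100 changed by 20 nt, with 8 false calls among 108. With weights by reads it made 18 false calls among 125, and with a replicate block 12 among 109. The simulated tails of a gene had the same spread in every library, whatever the reads, and no conditions shared by replicate number. Weights and block had nothing to correct there, so these counts do not judge them for the real libraries. With 1 N2 library shifted by 5 nt it found 17 and 70, with 14 false calls among 101. Centring those shifted data gave 22 and 77, with 8 false calls among 107. A list of calls therefore misses many changes of these sizes.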

Results

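The series used PAT-seq, a 3' end sequencing method, to count reads per gene and to measure mean poly(A) tail length per gene in early embryos of Caenorhabditis elegans. The 12 libraries formed 6 groups of 2. They were wild-type N2, 4 groups from worms fed bacteria that express double-stranded RNA against pos-1, gld-3, gld-2 or mex-5, and the mutant mex-6(pk440). POS-1, MEX-5 and MEX-6 are zinc finger RNA-binding proteins of the early embryo, GLD-2 is a cytoplasmic poly(A) polymerase and GLD-3 is its RNA-binding partner. The tables named the mex-6(pk440) columns as RNAi while the sample titles gave the allele, and the titles were followed. Gene reads per library ranged from 4613974 to 10229871, of which 35.4% to 56.7% fell on rRNA, so that 2282120 to 5294608 reads lay on other genes. Nothing in the labels stated that the 2 replicates of a group came from separate cultures, so the p-values measured the spread between these samples. The labels gave OP50 bacteria for N2 and HT115(DE3) bacteria for the RNAi groups, so food and RNAi changed together in every comparison of an RNAi group with N2.

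Each targeted gene was first read in every library. In pos-1 RNAi, pos-1 (chromosome V, 8414074 to 8414920, ce10) stood at 87.1 ± 62.9 CPM (reads scaled to library size; SD, n = 2; 132 and 42.7 in the single libraries) against 565 ± 84.7 in N2, a fitted 15.5% of N2 (log2 change -2.69 ± 0.38, SE; edgeR quasi-likelihood adjusted p = 0.0017; lower in 2 of 2 libraries). In gld-3 RNAi, gld-3 stood at 8.85 ± 0.577 against 105 ± 0.698 CPM, 8.46% of N2 (log2 change -3.56 ± 0.23, adjusted p = 4.3e-06). In gld-2 RNAi, gld-2 stood at 4.42 ± 1.57 against 10.3 ± 2.79 CPM, 44.3% of N2 (log2 change -1.17 ± 0.33, adjusted p = 0.019), on only 15 to 122 reads per library in these groups. That call was lost with the 4 samples of the 2 groups alone (adjusted p = 0.057), without N2 replicate 1 (adjusted p = 0.16) and without gld-2 RNAi replicate 2 (adjusted p = 0.13). In mex-5 RNAi, mex-5 stood at 36.4 ± 3.06 against 452 ± 5.75 CPM, 8.07% of N2 (log2 change -3.63 ± 0.22, adjusted p = 5.5e-07). The related gene mex-6 fell in mex-5 RNAi as well, to 8.75% of N2 (log2 change -3.51 ± 0.32, adjusted p = 1.6e-05). With mex-6(pk440) as the control in place of N2 the sign of that change turned (1.89), since mex-6 is lower still in that control. In mex-6(pk440), mex-6 stood at 5.04 ± 2.80 against 224 ± 27.3 CPM, 2.36% of N2 (log2 change -5.41 ± 0.36, adjusted p = 7.8e-06). There mex-5 differed from N2 by -0.29 ± 0.20 (adjusted p = 0.69). Of the called gene and comparison pairs named here and in the paragraphs that follow, both libraries of one group lay outside both of the other in 76 of 76 for expression and in 13 of 13 for tail length. Chance gives 33.3% for a gene taken at random, but these genes were taken for their calls, and many for this separation too, so the counts describe them and test nothing.

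**Figure D1:**
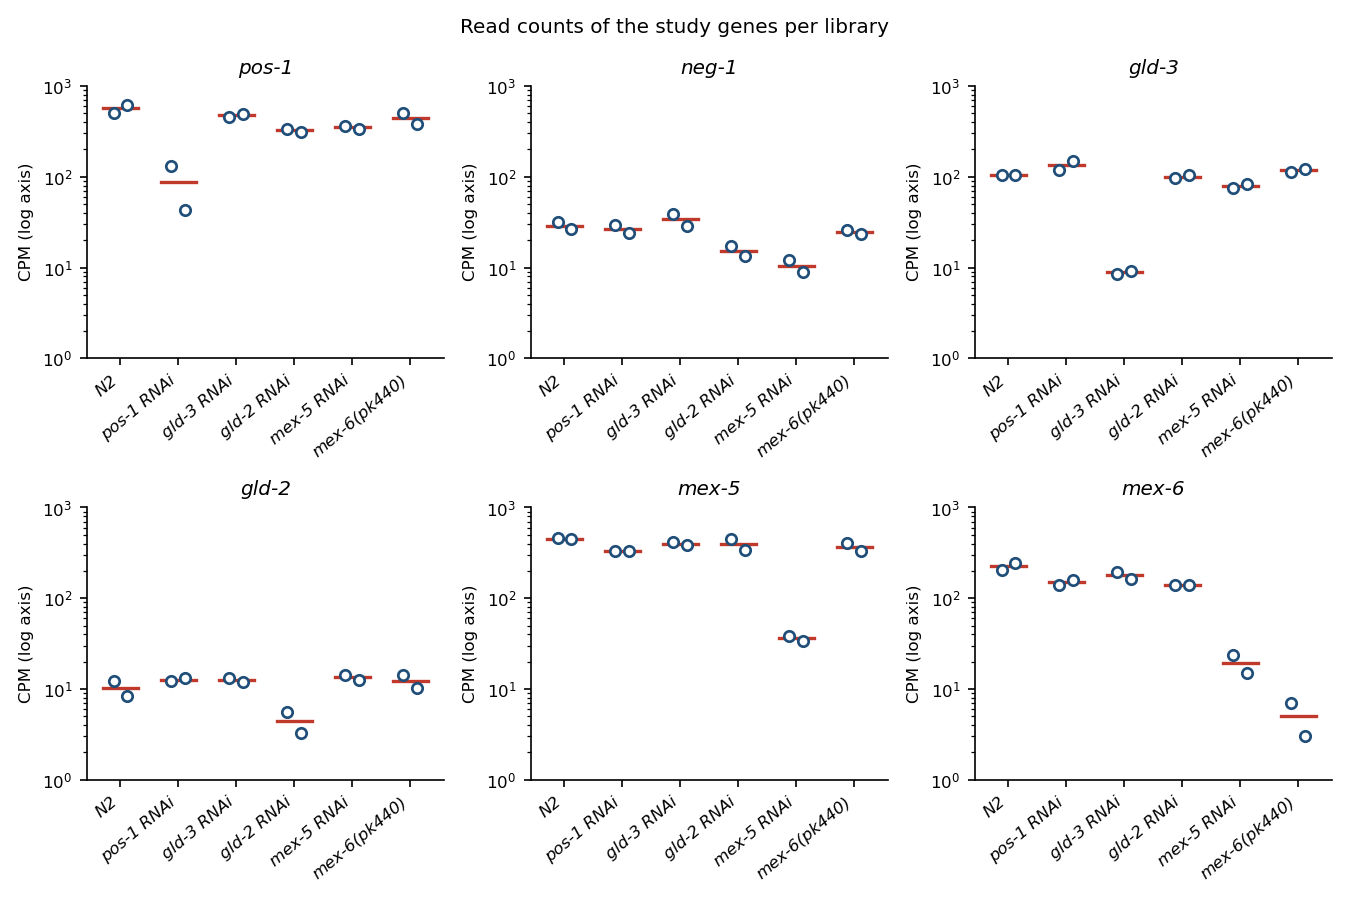
Expression in CPM of the 6 study genes in each of the 12 libraries, on a log axis; circles are libraries and bars are group means. Each targeted gene was lowest in the group in which it was targeted, except that mex-6 was also low in mex-5 RNAi.

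The factor in the series title, neg-1, is listed in the tables under its sequence name F32D1.6 (chromosome V, 4373912 to 4374832, minus strand, ce10), with a single poly(A) peak just downstream of the annotated gene. Its mean tail was 43.8 ± 4.05 nt in N2 (SD, n = 2), 48.7 ± 4.44 nt in pos-1 RNAi, 25.2 ± 0.585 nt in gld-3 RNAi, 37.96 ± 3.93 nt in gld-2 RNAi, 41.4 ± 5.60 nt in mex-5 RNAi and 44.6 ± 2.14 nt in mex-6(pk440). Both gld-3 RNAi libraries (25.6 and 24.8 nt) lay below the other 10. The direct comparison of pos-1 RNAi with gld-3 RNAi passed the test, with neg-1 tails 23.5 nt longer in pos-1 RNAi (SE 3.76; limma adjusted p = 0.030; longer in 2 of 2 libraries). That call was lost without pos-1 RNAi replicate 1 (adjusted p = 0.26), without pos-1 RNAi replicate 2 (adjusted p = 0.15), without gld-3 RNAi replicate 1 (adjusted p = 0.15), without gld-3 RNAi replicate 2 (adjusted p = 0.14) and on the neg-1 peak in place of the gene (adjusted p = 0.076). Against N2, the gld-3 RNAi difference was -18.6 ± 3.76 nt and did not pass uncentred (adjusted p = 0.15). It passed with each library centred on its median (-21.2 nt, adjusted p = 0.014), with values weighted by reads (-19.5 nt, adjusted p = 0.019), on the log2 scale (adjusted p = 0.035) and with libraries centred and scaled (adjusted p = 0.0098). The uncentred difference did not pass with a replicate block, with the 4 samples of the 2 groups alone or with mex-6(pk440) as the control. No library was left out of the centred fit, so how far that call rests on single libraries was not tested. The weighted test made 18 false calls among 125 on simulated data, against 8 among 108 for the unweighted test. Those data gave a gene the same spread in every library whatever its reads, so they could not judge the weights. The differences from N2 were 4.83 ± 3.76 nt in pos-1 RNAi (adjusted p = 0.60), -5.87 ± 3.76 nt in gld-2 RNAi (adjusted p = 0.46), -2.44 ± 3.76 nt in mex-5 RNAi (adjusted p = 0.80) and 0.810 ± 3.76 nt in mex-6(pk440) (adjusted p = 0.999). Tails of neg-1 in gld-3 RNAi and gld-2 RNAi differed by -12.8 ± 3.76 nt, which did not pass (adjusted p = 0.23) except on the log2 scale (adjusted p = 0.0462). The pos-1 RNAi and mex-5 RNAi tails differed by 7.27 ± 3.76 nt (adjusted p = 0.47), and the mex-5 RNAi and mex-6(pk440) tails by -3.25 ± 3.76 nt (adjusted p = 0.76).

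The amount of neg-1 transcript moved differently from its tail. It fell by 1.45 on the log2 scale in mex-5 RNAi (SE 0.28; edgeR quasi-likelihood adjusted p = 0.0016; lower in 2 of 2 libraries) and by 0.92 in gld-2 RNAi (adjusted p = 0.023). The latter call was lost without N2 replicate 1 (adjusted p = 0.12), without gld-2 RNAi replicate 1 (adjusted p = 0.084), without gld-2 RNAi replicate 2 (adjusted p = 0.15) and with mex-6(pk440) as the control (adjusted p = 0.087). In the other groups neg-1 did not pass, with log2 changes of -0.12 ± 0.26 in pos-1 RNAi (adjusted p = 0.81), 0.23 ± 0.26 in gld-3 RNAi (adjusted p = 0.61) and -0.24 ± 0.26 in mex-6(pk440) (adjusted p = 0.84). Levels were 1.33 ± 0.28 higher on the log2 scale in pos-1 RNAi than in mex-5 RNAi (adjusted p = 0.0025). They were 1.15 higher in gld-3 RNAi than in gld-2 RNAi (SE 0.27, adjusted p = 0.015), a call lost without gld-3 RNAi replicate 1 (adjusted p = 0.10), without gld-2 RNAi replicate 1 (adjusted p = 0.078) and without gld-2 RNAi replicate 2 (adjusted p = 0.096). Between mex-5 RNAi and mex-6(pk440) the difference was -1.22 ± 0.28 (adjusted p = 0.0070), a call lost without mex-5 RNAi replicate 2 (adjusted p = 0.082) and without mex-6(pk440) replicate 1 (adjusted p = 0.0545).

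**Figure D2:**
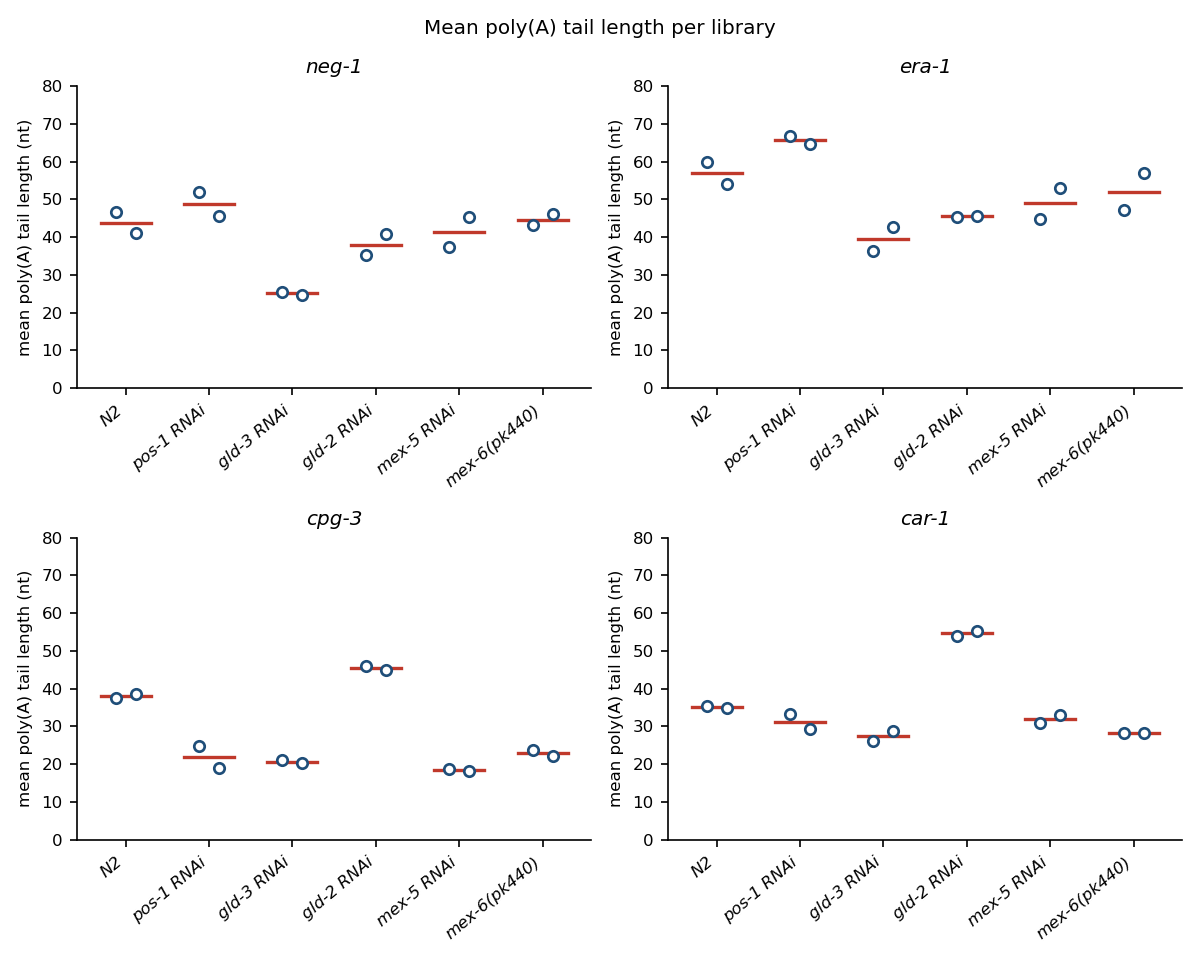
Mean poly(A) tail length in nt of neg-1, era-1, cpg-3 and car-1 in each of the 12 libraries; circles are libraries and bars are group means. Tails of neg-1 were shortest in the gld-3 RNAi libraries, and car-1 tails longest in the gld-2 RNAi libraries.

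The pos-1 RNAi comparison asked which transcripts need the posterior factor POS-1. Against N2, 1148 of 9403 genes passed the edgeR test, 441 higher and 707 lower. Whether pos-1 RNAi and N2 embryos differed in stage was not tested, so these changes were not assigned to pos-1 alone. Some genes of the intestinal fate fell. The intestinal GATA factor genes elt-7 (log2 change -2.76 ± 0.43, SE; n = 2, adjusted p = 0.0022) and elt-2 (-4.44 ± 0.83, adjusted p = 0.0046) were lower, as was ceh-51 (-1.80 ± 0.21, adjusted p = 6.6e-04), a homeobox gene of the MS mesoderm lineage. Among the endomesoderm and gut genes, 0 of 11 members were called higher and 6 lower, and 0 and 6 when adjusted over the list alone. Its median was -1.73 (camera adjusted p = 1.9e-04, adjusted p = 0.14 with an estimated correlation). Some anterior and epidermal genes rose, among them the head homeobox gene ceh-32 (1.69 ± 0.26, adjusted p = 0.0022) and the hypodermal GATA factor gene elt-3 (1.23 ± 0.22, adjusted p = 0.0042). Of the anterior and ectoderm genes, 5 of 14 members were called higher and 1 lower, and 6 and 2 when adjusted over the list alone. Its median was 0.61 (camera adjusted p = 0.024, adjusted p = 0.15 with an estimated correlation). The junction gene dlg-1 (1.54 ± 0.28, adjusted p = 0.0045), the epidermal antimicrobial peptide gene nlp-29 (2.93 ± 0.29, adjusted p = 3.9e-04) and mab-21 (1.64 ± 0.27, adjusted p = 0.0026) rose too, while the pharyngeal myosin gene myo-2 fell (-2.69 ± 0.42, adjusted p = 0.0022). The calls for elt-2 and elt-3 were lost with mex-6(pk440) as the control (adjusted p = 0.081 and 0.15).

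Transcripts of adult tissues were also lower in pos-1 RNAi. Yolk and adult intestine genes fell, with 10 of 12 members called lower, 11 when adjusted over the list alone. Its median was -2.51 (camera adjusted p = 1.0e-09, adjusted p = 0.18 with an estimated correlation). The cysteine protease gene cpr-6 changed by -2.56 ± 0.33 (adjusted p = 8.7e-04). Of the sperm genes, 17 of 29 were called lower, 25 when adjusted over the list alone (median -1.80, camera adjusted p = 4.7e-12, adjusted p = 0.15 with an estimated correlation), with msp-76, a major sperm protein gene, at -2.03 ± 0.32 (adjusted p = 0.0023). The propionate shunt gene acdh-1, whose transcription vitamin B12 represses, fell by 3.43 on the log2 scale (SE 0.54, adjusted p = 0.0023), one of 2 vitamin B12 and propionate genes called lower of 11 (3 adjusted over the list alone; median -0.26, camera adjusted p = 0.082, adjusted p = 0.28 with an estimated correlation). Maternal cell fate regulators had 1 of 17 members called higher, 0 adjusted over the list alone (median 0.40, camera adjusted p = 0.024, adjusted p = 0.18 with an estimated correlation), and histone genes 2 of 26, 0 adjusted over the list alone. Its median was 0.32 (camera adjusted p = 0.026, adjusted p = 0.35 with an estimated correlation). The number called dropped without N2 replicate 2 (401), without pos-1 RNAi replicate 2 (355), with the 4 samples alone (390, of which 226 higher and 164 lower) and with mex-6(pk440) as the control (436, of which 91 higher and 345 lower). Without N2 replicate 1 it was 783 (219 higher, 564 lower).

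**Figure D3:**
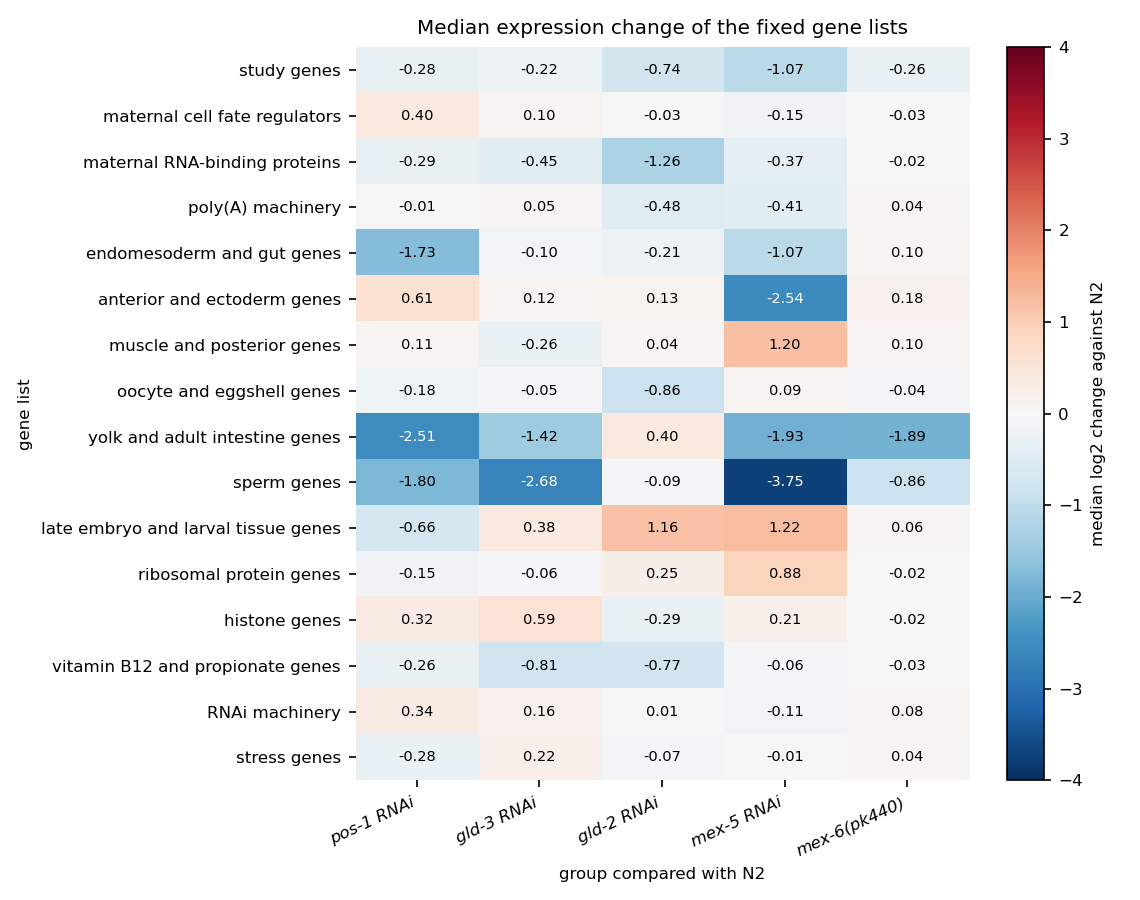
Median log2 expression change against N2 of the 16 gene lists fixed before the data were examined, one column for each group compared with N2. Endomesoderm and gut genes had a median of -1.73 in pos-1 RNAi, and sperm genes had medians from -3.75 to -0.09.

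Of 5471 genes tested for tail length in pos-1 RNAi, 1 passed limma (635 at an unadjusted p under 0.05), the chondroitin proteoglycan gene cpg-3. On data simulated for this comparison the test found 23 of 100 changes of 10 nt and 77 of 100 of 20 nt, so the low count does not show that tails were unchanged. Its mean tail was 22.0 ± 4.09 nt against 38.1 ± 0.659 nt in N2 (difference -16.08 ± 2.14 nt, SE; n = 2, adjusted p = 0.044). The call was lost, leaving 0 genes, without N2 replicate 2, without pos-1 RNAi replicate 2, with the 4 samples alone, with weights or with a replicate block, where the adjusted p for cpg-3 ran from 0.058 to 0.65. Against mex-6(pk440) as the control the difference itself was small (-0.988 nt, adjusted p = 0.88). In other settings the count was 3 (2 longer, 1 shorter) with at least 50 reads per library, 3 (1 longer, 2 shorter) on the log2 scale, 8 (7 longer, 1 shorter) without N2 replicate 1 and 3 (0 longer, 3 shorter) without pos-1 RNAi replicate 1. Oocyte and eggshell genes, the list that holds cpg-3, had 1 of 15 members called shorter, 7 when adjusted over the list alone. Its median was -2.11 (camera adjusted p = 7.2e-08, adjusted p = 0.14 with an estimated correlation).

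The gld-3 RNAi comparison asked what the partner of the poly(A) polymerase GLD-2 maintains. Against N2, 760 genes passed, 382 higher and 378 lower. Whether gld-3 RNAi and N2 embryos differed in stage was not tested. Some maternal RNA-binding protein genes were lower, with the Pumilio family gene puf-11 at a log2 change of -1.31 ± 0.23 (SE; n = 2, adjusted p = 0.0054). In that list 0 of 25 members were called higher and 5 lower, and 0 and 10 when adjusted over the list alone. Its median was -0.45 (camera adjusted p = 1.3e-04, adjusted p = 0.20 with an estimated correlation). The proteoglycan gene cpg-3 rose (1.46 ± 0.22, adjusted p = 0.0029). Some histone genes were higher, with 6 of 26 called, 9 when adjusted over the list alone. Its median was 0.59 (camera adjusted p = 3.4e-05, adjusted p = 0.20 with an estimated correlation). Late embryo and larval tissue genes had 3 of 15 called higher, 5 when adjusted over the list alone. Its median was 0.38 (camera adjusted p = 0.028, adjusted p = 0.26 with an estimated correlation). Of the endomesoderm and gut genes, 0 of 11 members were called higher and 0 lower, and 0 and 0 when adjusted over the list alone. Its median was -0.10 (camera adjusted p = 0.84, adjusted p = 0.88 with an estimated correlation).

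Sperm and yolk transcripts were lower in gld-3 RNAi too. Of the sperm genes 24 of 29 were called lower, 27 when adjusted over the list alone (median -2.68, camera adjusted p = 2.1e-19, adjusted p = 0.14 with an estimated correlation), and msp-76 changed by -3.13 ± 0.35 (adjusted p = 7.6e-04). Of the yolk and adult intestine genes 6 of 12 were called lower, 9 when adjusted over the list alone. Its median was -1.42 (camera adjusted p = 7.4e-05, adjusted p = 0.32 with an estimated correlation). The propionate shunt gene acdh-1 changed by -3.53 ± 0.55 (adjusted p = 0.0035); in its list 2 of 11 were called lower, 3 when adjusted over the list alone. Its median was -0.81 (camera adjusted p = 5.1e-04, adjusted p = 0.19 with an estimated correlation). The count dropped without N2 replicate 2 (125), without gld-3 RNAi replicate 2 (211), with the 4 samples alone (313) and with mex-6(pk440) as the control (48, of which 14 higher and 34 lower), and it rose with a replicate block (1206) and with no low-count filter (1279). Without N2 replicate 1 it was 543 (214 higher, 329 lower).

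Tail lengths in gld-3 RNAi showed 1 call (841 at an unadjusted p under 0.05), again cpg-3, at 20.7 ± 0.635 nt against 38.1 ± 0.659 nt in N2 (-17.4 ± 2.14 nt, adjusted p = 0.020). With each library centred on its median 48 (9 longer, 39 shorter) genes passed, neg-1 among them, and 129 (15 longer, 114 shorter) passed when the libraries were also scaled to one spread. The study genes mex-5 (-14.8 nt, limma adjusted p = 0.014) and pos-1 (-11.2 nt, adjusted p = 0.032) passed after centring as well. Tails of mex-6 (-9.31 nt, adjusted p = 0.054) and gld-3 (-1.11 nt, adjusted p = 0.81) did not. Maternal RNA-binding protein genes had 0 of 21 called shorter, 8 when adjusted over the list alone (median -3.63, camera adjusted p = 9.2e-10, adjusted p = 0.26 with an estimated correlation); after centring these were 5 and 14. Among the study genes 0 of 5 were called shorter, 4 when adjusted over the list alone. Its median was -8.68 (camera adjusted p = 1.6e-04, adjusted p = 0.26 with an estimated correlation). The cpg-3 call was lost without N2 replicate 2, without gld-3 RNAi replicate 1, without gld-3 RNAi replicate 2 and with the 4 samples alone (adjusted p from 0.069 to 0.31), where the difference stayed between -17.8 and -16.9 nt. Against mex-6(pk440) as the control it shrank to -2.28 nt (adjusted p = 0.63). The count was 6 (4 longer, 2 shorter) without N2 replicate 1, 2 without N2 replicate 2, 0 without either gld-3 RNAi replicate, 14 (3 longer, 11 shorter) with weights, 9 on the log2 scale, 3 with at least 50 reads and 2 with a replicate block.

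The gld-2 RNAi comparison asked what changes when the polymerase gene is depleted, here to a fitted 44.3% of N2. Against N2, 2551 genes passed, 1352 higher and 1199 lower. A difference in embryo stage between gld-2 RNAi and N2 was not tested. The changes of maternal and late genes were therefore not assigned to gld-2 alone. Maternal RNA-binding protein genes fell, led by the Pumilio family genes puf-5 (log2 change -2.64 ± 0.20, SE; n = 2, adjusted p = 2.8e-05) and puf-3 (-2.26 ± 0.22, adjusted p = 7.4e-05), the Y-box protein gene cey-3 (-2.59 ± 0.26, adjusted p = 1.0e-04) and gld-1 (-1.78 ± 0.19, adjusted p = 1.5e-04). In that list 0 of 25 members were called higher and 19 lower, and 0 and 20 when adjusted over the list alone. Its median was -1.26 (camera adjusted p = 3.1e-12, adjusted p = 0.040 with an estimated correlation). Several oocyte and eggshell genes fell as well, such as egg-1 (-2.26 ± 0.27, adjusted p = 2.3e-04) and cpg-1 (-1.78 ± 0.22, adjusted p = 2.7e-04), with 10 of 17 called lower, 10 when adjusted over the list alone. Its median was -0.86 (camera adjusted p = 5.1e-04, adjusted p = 0.10 with an estimated correlation). The Wnt ligand gene mom-2 (-1.46 ± 0.22, adjusted p = 6.9e-04) and rnp-8, which encodes another GLD-2 partner (-1.32 ± 0.25, adjusted p = 0.0025), were lower; 7 of 19 poly(A) machinery genes and 4 of 17 maternal cell fate regulators were called lower, 8 and 4 when adjusted over the list alone, with camera adjusted p = 0.069 and 0.52. Late embryo and larval tissue genes rose, among them the synaptic vesicle gene rab-3 (2.77 ± 0.31, adjusted p = 1.9e-04), the body wall myosin gene myo-3 (1.44 ± 0.21, adjusted p = 5.6e-04) and the cuticle collagen gene sqt-3 (1.12 ± 0.17, adjusted p = 8.5e-04). In that list 12 of 15 members were called higher and 0 lower, and 14 and 0 when adjusted over the list alone. Its median was 1.16 (camera adjusted p = 6.5e-07, adjusted p = 0.040 with an estimated correlation).

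Adult transcripts in gld-2 RNAi stayed near the N2 level. The yolk and adult intestine genes had a median change of 0.40, with 1 called higher and 0 lower of 12 (0 and 0 adjusted over the list alone; camera adjusted p = 0.23), and the sperm genes a median of -0.09, with 1 of 29 called lower (0 adjusted over the list alone; camera adjusted p = 0.71). The gene acdh-1 fell by 2.09 on the log2 scale (SE 0.50, adjusted p = 0.0096), a call lost without gld-2 RNAi replicate 2 (-1.71, adjusted p = 0.090), and 3 of 11 members of its list were called lower, 3 when adjusted over the list alone. Its median was -0.77 (camera adjusted p = 0.042, adjusted p = 0.29 with an estimated correlation). Ribosomal protein genes had 3 called higher and 1 lower of 66 (0 and 0 adjusted over the list alone; median 0.25, camera adjusted p = 0.028, adjusted p = 0.68 with an estimated correlation). The number called was 1293 without N2 replicate 1, 1572 without N2 replicate 2, 1184 (849 higher, 335 lower) without gld-2 RNAi replicate 1 and 1333 without gld-2 RNAi replicate 2.

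In gld-2 RNAi, 13 genes passed the tail test (903 at an unadjusted p under 0.05), 13 of them longer than in N2 and 0 shorter. The maternal RNA-binding protein gene car-1 had a mean tail of 54.6 ± 0.962 nt against 35.2 ± 0.355 nt (19.4 ± 1.88 nt, adjusted p = 0.0017), a call lost without gld-2 RNAi replicate 2 (adjusted p = 0.071). The mitochondrial chaperonin gene hsp-60 had 52.2 ± 3.82 nt against 32.6 ± 4.44 nt (19.6 ± 2.65 nt, adjusted p = 0.017), a call lost with the 4 samples alone, without N2 replicate 2 and without gld-2 RNAi replicate 2 (adjusted p = 0.15, 0.25 and 0.26). Stress genes had 1 of 9 called longer, 6 when adjusted over the list alone. Its median was 9.66 (camera adjusted p = 9.8e-05, adjusted p = 0.19 with an estimated correlation). The direction of the calls depended on the centring, with 73 (28 longer, 45 shorter) passing after centring on library medians and 240 (85 longer, 155 shorter) after centring and scaling. The count was 41 without N2 replicate 1, 1 without N2 replicate 2, 6 without gld-2 RNAi replicate 1, 0 without gld-2 RNAi replicate 2, 1 with the 4 samples alone, 44 with at least 50 reads, 20 with weights, 60 on the log2 scale and 87 with mex-6(pk440) as the control.

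The mex-5 RNAi comparison asked what follows depletion of mex-5, an anterior factor, in libraries where mex-6 was also down to 8.75% of N2, so its changes were not assigned to either gene alone. Nor was a difference in embryo stage from N2 tested. Against N2, 2900 genes passed, 1727 higher and 1173 lower. Several anterior genes fell, among them ceh-32 (log2 change -2.81 ± 0.29, SE; n = 2, adjusted p = 2.7e-05), the NeuroD-type gene cnd-1 (-3.36 ± 0.43, adjusted p = 1.0e-04) and the T-box gene tbx-38 (-3.30 ± 0.51, adjusted p = 3.6e-04), while elt-3 rose (2.31 ± 0.23, adjusted p = 1.9e-05). In that list 1 of 14 members were called higher and 7 lower, and 1 and 8 when adjusted over the list alone. Its median was -2.54 (camera adjusted p = 0.0033, adjusted p = 0.061 with an estimated correlation). Muscle and posterior genes rose, such as the MyoD-type gene hlh-1 (2.22 ± 0.34, adjusted p = 3.3e-04) and the Wnt gene cwn-1 (1.99 ± 0.41, adjusted p = 0.0026), with 7 of 11 called higher, 8 when adjusted over the list alone. Its median was 1.20 (camera adjusted p = 0.0035, adjusted p = 0.061 with an estimated correlation). Late tissue genes rose with them, including myo-3 (2.67 ± 0.21, adjusted p = 5.7e-06), with 10 of 15 called higher, 11 when adjusted over the list alone. Its median was 1.22 (camera adjusted p = 2.4e-04, adjusted p = 0.061 with an estimated correlation). Endomesoderm and gut genes went both ways, the intestinal filament gene ifb-2 rising (2.84 ± 0.33, adjusted p = 5.2e-05) and the pharyngeal FoxA gene pha-4 (-1.77 ± 0.27, adjusted p = 3.1e-04) and ceh-51 (-1.36 ± 0.21, adjusted p = 3.7e-04) falling; the list of 11 had 1 called higher and 3 lower (1 and 3 adjusted over the list alone; camera adjusted p = 0.062).

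Ribosomal protein genes rose in mex-5 RNAi, with rpl-3 at 1.25 ± 0.22 (adjusted p = 8.3e-04); 43 of 66 were called higher, 52 when adjusted over the list alone. Its median was 0.88 (camera adjusted p = 3.4e-11, adjusted p = 0.22 with an estimated correlation). A few maternal RNA-binding protein genes fell, such as the germline helicase gene glh-1 (-1.72 ± 0.26, adjusted p = 3.0e-04), with 6 of 25 called lower, 6 when adjusted over the list alone. Its median was -0.37 (camera adjusted p = 0.0068, adjusted p = 0.23 with an estimated correlation). Study genes had 3 of 6 called lower, 3 when adjusted over the list alone. Its median was -1.07 (camera adjusted p = 0.0033, adjusted p = 0.090 with an estimated correlation). The sperm genes were lower here as well, with 27 of 29 called, 29 when adjusted over the list alone. Its median was -3.75 (camera adjusted p = 1.4e-17, adjusted p = 0.061 with an estimated correlation). Of the 12 yolk and adult intestine genes, 7 were called lower with 2 higher, 7 and 2 when adjusted over the list alone. Its median was -1.93 (camera adjusted p = 0.036, adjusted p = 0.56 with an estimated correlation). The gene acdh-1 changed by -3.43 ± 0.56 (adjusted p = 5.4e-04), while alh-8, another gene of the propionate shunt, rose (1.22 ± 0.21, adjusted p = 7.4e-04). The number called was 1894 without N2 replicate 1, 1855 (1343 higher, 512 lower) without mex-5 RNAi replicate 2 and 1959 (1371 higher, 588 lower) with mex-6(pk440) as the control.

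In mex-5 RNAi, 22 genes passed the tail test (838 at an unadjusted p under 0.05), 15 longer and 7 shorter. The Patched receptor gene ptc-1 had a mean tail of 41.1 ± 1.45 nt against 26.9 ± 1.09 nt in N2 (14.2 ± 1.65 nt, adjusted p = 0.0056), and cpg-3 one of 18.4 ± 0.246 nt (-19.6 ± 2.14 nt, adjusted p = 0.0056). Both calls were lost without mex-5 RNAi replicate 2 (adjusted p = 0.062 and 0.062) and with the 4 samples alone (adjusted p = 0.23 and 0.17), and that of cpg-3 with mex-6(pk440) as the control, where it shrank to -4.54 nt (adjusted p = 0.43). Oocyte and eggshell genes had 1 of 15 called shorter, 7 when adjusted over the list alone. Its median was -1.69 (camera adjusted p = 1.1e-05, adjusted p = 0.38 with an estimated correlation). After centring 94 (30 longer, 64 shorter) genes passed, and 308 (96 longer, 212 shorter) after centring and scaling. The count was 6 (1 longer, 5 shorter) without N2 replicate 2, 2 (1 longer, 1 shorter) without mex-5 RNAi replicate 1, 0 without mex-5 RNAi replicate 2 or with the 4 samples alone, 52 with at least 50 reads, 16 (7 longer, 9 shorter) with weights, 98 on the log2 scale, 10 (5 longer, 5 shorter) with a replicate block and 4 with mex-6(pk440) as the control.

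The mex-6(pk440) comparison asked what the loss of MEX-6 alone does. By edgeR, 2 genes passed (860 at an unadjusted p under 0.05), mex-6 itself and the collagen gene col-178, which stood at 4.08 ± 0.882 CPM against 144 ± 46.2 CPM in N2 (log2 change -5.17 ± 0.63, adjusted p = 0.0068). That gene was also low in pos-1 RNAi (17.1 ± 17.1 CPM), gld-3 RNAi (17.6 ± 0.260) and mex-5 RNAi (7.81 ± 3.68) and high in gld-2 RNAi (179 ± 4.06). A low level was thus not particular to mex-6(pk440), and the high and low groups were those of the adult transcripts described below. The size of the fall did not follow them, since col-178 was lowest in mex-6(pk440), where neither adult list had its lowest mean. The col-178 call was lost without either mex-6(pk440) replicate (adjusted p = 0.31 without replicate 1 and 0.33 without replicate 2, with 1 gene left in each), and 9 genes passed without N2 replicate 1. Other settings called more, 74 (18 higher, 56 lower) by DESeq2, 44 (11 higher, 33 lower) with a replicate block, 34 (1 higher, 33 lower) with the 4 samples alone and 172 (34 higher, 138 lower) with no low-count filter. Yolk and adult intestine genes had 0 of 12 called lower over all genes and 10 when adjusted over the list alone. Its median was -1.89 (camera adjusted p = 6.0e-12, adjusted p = 0.32 with an estimated correlation). Sperm genes had 0 of 29 called lower, and 0 when adjusted over the list alone. Its median was -0.86 (camera adjusted p = 1.2e-09, adjusted p = 0.32 with an estimated correlation). For tail length limma called 0 genes, with 195 at an unadjusted p under 0.05, and 0 to 1 in the other settings; oocyte and eggshell genes had 0 of 15 called shorter, 6 when adjusted over the list alone. Its median was -3.22 (camera adjusted p = 8.4e-09, adjusted p = 0.20 with an estimated correlation).

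**Figure D4:**
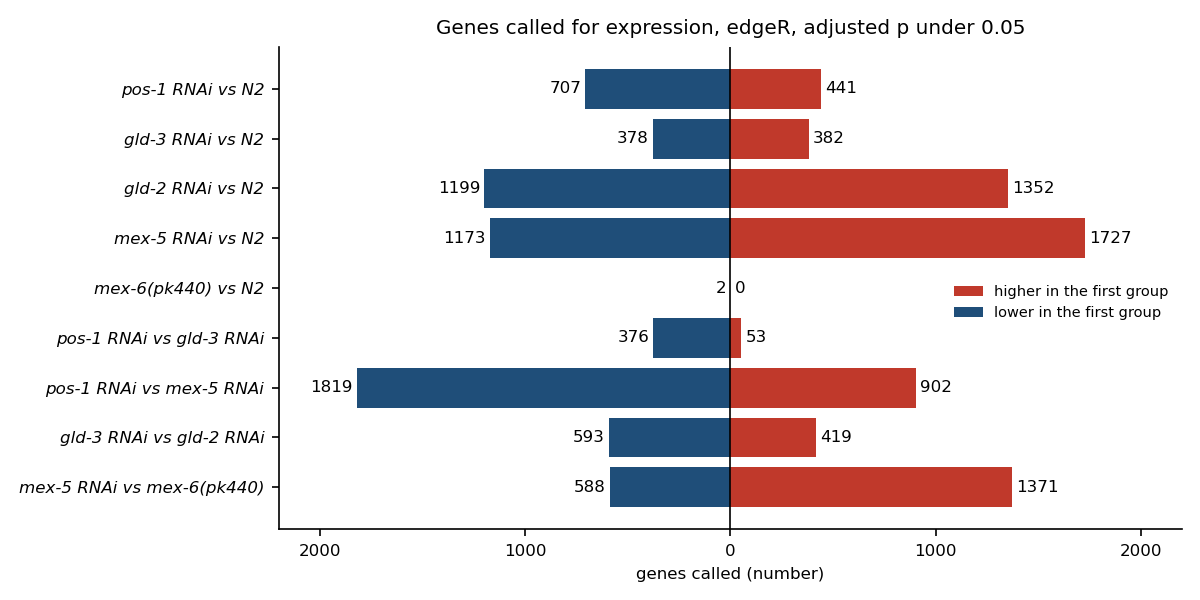
Number of genes called higher or lower for expression in the 9 comparisons (edgeR, adjusted p under 0.05, 9403 genes tested), with bars to the right for genes higher in the first group named. Counts ran from 2 in mex-6(pk440) vs N2 to 2900 in mex-5 RNAi vs N2.

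Across the groups, the lists of adult transcripts split the libraries. The mean of the 12 yolk and adult intestine genes above 1 CPM on average, in log2 (CPM + 0.5), was 4.39 ± 0.25 in N2 (SD, n = 2) and 4.82 ± 0.02 in gld-2 RNAi. It was 2.15 ± 0.83 in pos-1 RNAi, 3.03 ± 0.28 in gld-3 RNAi, 3.26 ± 0.16 in mex-5 RNAi and 2.87 ± 0.30 in mex-6(pk440). The 24 sperm genes above 1 CPM had means of 2.82 ± 0.33 in N2, 2.75 ± 0.06 in gld-2 RNAi, 2.02 ± 0.23 in mex-6(pk440), 1.14 ± 0.38 in pos-1 RNAi, 0.85 ± 0.18 in gld-3 RNAi and -0.01 ± 0.16 in mex-5 RNAi. Tails of cpg-3 followed the same division, at 38.1 ± 0.659 nt in N2 and 45.5 ± 0.648 nt in gld-2 RNAi but 23.0 ± 1.12 nt in mex-6(pk440).

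**Figure D5:**
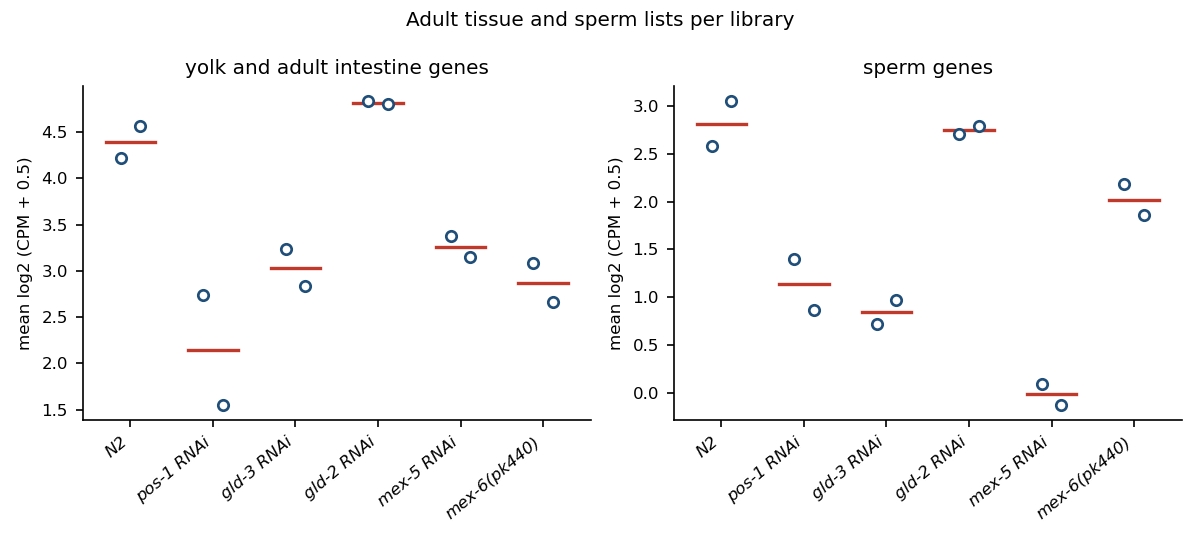
Mean log2 (CPM + 0.5) of the yolk and adult intestine genes (12 members) and of the sperm genes (24 members) in each of the 12 libraries; circles are libraries and bars are group means. For the first list, both N2 and both gld-2 RNAi libraries lay above the other 8.

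The pos-1 RNAi and gld-3 RNAi groups were compared directly, since the title sets POS-1 against GLD-3. For expression 429 genes differed, 53 higher and 376 lower in pos-1 RNAi. Several endomesoderm and gut genes were lower in pos-1 RNAi, ceh-51 by 2.12 on the log2 scale (SE 0.21; n = 2, adjusted p = 6.6e-05), with 5 of 11 called, 7 when adjusted over the list alone. Its median was -1.98 (camera adjusted p = 1.2e-04, adjusted p = 0.095 with an estimated correlation). Also lower were cpg-3 (-2.28 ± 0.23, adjusted p = 6.3e-05), cpr-6 (-2.99 ± 0.32, adjusted p = 1.4e-04), rab-3 (-2.27 ± 0.33, adjusted p = 0.0013) and the Hsp90 gene daf-21 (-1.27 ± 0.20, adjusted p = 0.0022). Late embryo and larval tissue genes had 5 of 15 called lower, 7 when adjusted over the list alone (median -0.33, camera adjusted p = 0.0029, adjusted p = 0.16 with an estimated correlation), and yolk and adult intestine genes 3 of 12, 5 when adjusted over the list alone. Its median was -0.87 (camera adjusted p = 0.0019, adjusted p = 0.32 with an estimated correlation). The sperm list had 0 of 29 called higher (0 adjusted over the list alone; median 0.56, camera adjusted p = 0.014, adjusted p = 0.36 with an estimated correlation). The count was 241 without pos-1 RNAi replicate 1, 146 without pos-1 RNAi replicate 2, 211 without gld-3 RNAi replicate 2, 108 with the 4 samples alone and 660 with no low-count filter.

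In the same pair, 15 genes differed in tail length (470 at an unadjusted p under 0.05), all 15 longer in pos-1 RNAi. Beside neg-1 they included era-1, at 65.7 ± 1.61 nt in pos-1 RNAi and 39.4 ± 4.49 nt in gld-3 RNAi (26.3 ± 3.61 nt, SE; n = 2, adjusted p = 0.011). The era-1 call was lost without pos-1 RNAi replicate 1 (adjusted p = 0.22), without pos-1 RNAi replicate 2 (adjusted p = 0.15) and without gld-3 RNAi replicate 1 (adjusted p = 0.12). The count was 2 without pos-1 RNAi replicate 1, 0 without pos-1 RNAi replicate 2, 1 without gld-3 RNAi replicate 1, 9 without gld-3 RNAi replicate 2 and 55 with weights. With centring 78 (62 longer, 16 shorter) genes passed, and 69 (56 longer, 13 shorter) with centring and scaling.

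The pos-1 RNAi and mex-5 RNAi groups were depleted of the posterior factor pos-1 and of the anterior factors mex-5 and mex-6, respectively. For expression 2721 genes differed, 902 higher and 1819 lower in pos-1 RNAi. Several anterior genes stood higher in pos-1 RNAi, ceh-32 by 4.50 on the log2 scale (SE 0.31; n = 2, adjusted p = 1.2e-06) and tbx-38 by 4.44 (adjusted p = 2.0e-05), with 8 of 14 called higher and 1 lower, 8 and 1 when adjusted over the list alone. Its median was 2.22 (camera adjusted p = 2.8e-05, adjusted p = 0.0457 with an estimated correlation). Lower in pos-1 RNAi were ifb-2 (-4.56 ± 0.37, adjusted p = 2.3e-06), myo-3 (-2.62 ± 0.21, adjusted p = 2.3e-06) and rpl-37 (-1.18 ± 0.19, adjusted p = 4.5e-04), the last with 50 of 66 ribosomal protein genes, 60 when adjusted over the list alone. Its median was -1.01 (camera adjusted p = 3.7e-13, adjusted p = 0.15 with an estimated correlation). Muscle and posterior genes had 5 of 11 called lower, 6 when adjusted over the list alone (camera adjusted p = 0.066). Sperm genes had 13 of 29 called higher, 15 when adjusted over the list alone. Its median was 1.91 (camera adjusted p = 3.3e-06, adjusted p = 0.15 with an estimated correlation). For tail length 46 genes passed (654 at an unadjusted p under 0.05), 29 longer and 17 shorter in pos-1 RNAi, and 147 (79 longer, 68 shorter) after centring. The difference for ptc-1 was -13.7 ± 1.65 nt (adjusted p = 0.0061). That call was lost without mex-5 RNAi replicate 2 and without either pos-1 RNAi replicate (adjusted p from 0.059 to 0.12). The tail count was 0 without either pos-1 RNAi replicate, 3 (1 longer, 2 shorter) without mex-5 RNAi replicate 1, 1 (1 longer, 0 shorter) without mex-5 RNAi replicate 2, 12 with the 4 samples alone, 28 with a replicate block and 41 (20 longer, 21 shorter) on the log2 scale.

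The gld-3 RNAi and gld-2 RNAi groups target the partners of one polymerase complex, but unequally, with 8.46% of gld-3 and 44.3% of gld-2 left. For expression 1012 genes differed, 419 higher and 593 lower in gld-3 RNAi. Several maternal RNA-binding protein genes stood higher in gld-3 RNAi, among them puf-5 (2.48 ± 0.20, SE; n = 2, adjusted p = 4.3e-05) and gld-1 (1.34 ± 0.19, adjusted p = 0.0015), with 13 of 25 called, 14 when adjusted over the list alone. Its median was 0.88 (camera adjusted p = 3.8e-09, adjusted p = 0.0502 with an estimated correlation). So did some oocyte and eggshell genes such as cpg-1 (2.57 ± 0.23, adjusted p = 1.1e-04), with 6 of 17, 8 when adjusted over the list alone. Its median was 0.57 (camera adjusted p = 8.4e-06, adjusted p = 0.0502 with an estimated correlation). Several histone genes such as his-60 were higher too (1.65 ± 0.26, adjusted p = 0.0024), with 13 of 26, 16 when adjusted over the list alone. Its median was 1.06 (camera adjusted p = 1.8e-08, adjusted p = 0.062 with an estimated correlation). Sperm genes were lower in gld-3 RNAi, with msp-76 at -3.53 ± 0.35 (adjusted p = 2.6e-04) and 20 of 29 called, 25 when adjusted over the list alone. Its median was -2.43 (camera adjusted p = 1.3e-16, adjusted p = 0.0502 with an estimated correlation). Of the yolk and adult intestine genes 8 of 12 were called lower, 10 when adjusted over the list alone. Its median was -2.01 (camera adjusted p = 1.4e-07, adjusted p = 0.17 with an estimated correlation). Late embryo and larval tissue genes had 6 of 15 called lower, 10 when adjusted over the list alone. Its median was -0.94 (camera adjusted p = 6.9e-06, adjusted p = 0.0502 with an estimated correlation). The count was 449 without gld-3 RNAi replicate 1, 664 without gld-3 RNAi replicate 2, 258 (52 higher, 206 lower) without gld-2 RNAi replicate 1, 671 without gld-2 RNAi replicate 2 and 1649 (884 higher, 765 lower) with no low-count filter.

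Tails of the same pair differed for 31 genes (510 at an unadjusted p under 0.05), all 31 shorter in gld-3 RNAi. The difference was -27.2 ± 1.88 nt for car-1 (SE; n = 2, adjusted p = 4.2e-05), -24.8 ± 2.14 nt for cpg-3 (adjusted p = 2.4e-04), -12.6 ± 1.40 nt for the P-body helicase gene cgh-1 (adjusted p = 0.0023) and -22.8 ± 2.65 nt for hsp-60 (adjusted p = 0.0028). The car-1 and cpg-3 calls held in every setting run for them. The short cpg-3 tail of gld-3 RNAi (20.7 nt) was not particular to that group. It was 22.0 nt in pos-1 RNAi, 18.4 nt in mex-5 RNAi and 23.0 nt in mex-6(pk440). With the 4 samples alone those of cgh-1 (adjusted p = 0.061) and hsp-60 (adjusted p = 0.061) were lost, and that of hsp-60 also without gld-2 RNAi replicate 2 (adjusted p = 0.075). Maternal RNA-binding protein genes had 4 of 21 called shorter in gld-3 RNAi, 6 when adjusted over the list alone (median -4.60, camera adjusted p = 1.1e-04, adjusted p = 0.60 with an estimated correlation), and stress genes 4 of 9, 4 when adjusted over the list alone. Its median was -6.02 (camera adjusted p = 1.1e-04, adjusted p = 0.39 with an estimated correlation). With centring 62 (14 longer, 48 shorter) genes passed, and 69 (18 longer, 51 shorter) with centring and scaling. The count was 7 without gld-3 RNAi replicate 1, 15 without gld-3 RNAi replicate 2, 10 without gld-2 RNAi replicate 1, 3 without gld-2 RNAi replicate 2, 2 with the 4 samples alone and 61 on the log2 scale.

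The mex-5 RNAi libraries were low in both mex-5 and mex-6 (8.07% and 8.75% of N2), and the mex-6(pk440) libraries in mex-6 (2.36%), so this comparison sets both against one. RNAi differed between these groups too, and the food of mex-6(pk440) is not given by the labels. Effects of feeding and of the 2 genes cannot be told apart here. For expression 1959 genes differed, 1371 higher and 588 lower in mex-5 RNAi. Lower in mex-5 RNAi were ceh-32 (-3.01 ± 0.29, SE; n = 2, adjusted p = 4.0e-05), cnd-1 (-3.46 ± 0.43, adjusted p = 1.2e-04) and pha-4 (-1.96 ± 0.27, adjusted p = 2.5e-04), and higher were myo-3 (2.32 ± 0.21, adjusted p = 2.6e-05), ifb-2 (2.85 ± 0.33, adjusted p = 8.1e-05) and rpl-31 (1.02 ± 0.20, adjusted p = 0.0028). Anterior and ectoderm genes had 6 of 14 called lower and 1 higher, 8 and 1 when adjusted over the list alone. Its median was -2.76 (camera adjusted p = 1.7e-04, adjusted p = 0.067 with an estimated correlation). Ribosomal protein genes had 50 of 66 called higher, 59 when adjusted over the list alone. Its median was 0.92 (camera adjusted p = 1.5e-15, adjusted p = 0.17 with an estimated correlation). Sperm genes had 20 of 29 called lower, 24 when adjusted over the list alone. Its median was -3.26 (camera adjusted p = 7.8e-15, adjusted p = 0.067 with an estimated correlation). The transcript of mex-6 stood 1.89 higher on the log2 scale in mex-5 RNAi than in mex-6(pk440) (SE 0.34, adjusted p = 0.0015). The count was 1222 without mex-5 RNAi replicate 2, 931 without mex-6(pk440) replicate 1 and 1249 without mex-6(pk440) replicate 2. For tail length 4 genes passed (644 at an unadjusted p under 0.05), 3 longer and 1 shorter in mex-5 RNAi. The count was 0 without mex-5 RNAi replicate 1, without mex-5 RNAi replicate 2, without mex-6(pk440) replicate 1, without mex-6(pk440) replicate 2 or with the 4 samples alone, and 3 (3 longer, 0 shorter) with weights. After centring it was 47 (13 longer, 34 shorter), after centring and scaling 135 (49 longer, 86 shorter), and on the log2 scale 29 (25 longer, 4 shorter).

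The medians of whole libraries were compared because size selection can shift every tail. Over the 5471 genes, the mean of the library medians was 42.3 ± 2.69 nt in N2 (SD, n = 2), and the other groups differed from it by 3.11 nt (pos-1 RNAi), 2.51 nt (gld-3 RNAi), 3.59 nt (gld-2 RNAi), 2.21 nt (mex-5 RNAi) and 0.000404 nt (mex-6(pk440)). With 2 libraries per group the smallest exact permutation p is 0.333, so a permutation test could not pass. A linear model on the 12 medians with 6 residual degrees of freedom, chosen after the data were seen, gave an SE of 1.92 nt for each difference, with adjusted p = 0.37 in the 4 RNAi groups and 0.9998 in mex-6(pk440). Changes in tail length against the shared N2 libraries were then compared between groups, across genes, which are not independent replicates. Pearson's r was 0.561 for pos-1 and gld-3, 0.438 for pos-1 and gld-2, 0.559 for gld-3 and gld-2, 0.482 for pos-1 and mex-5, and 0.468 for mex-5 and mex-6(pk440), while 40 simulated pairs of unchanged groups that shared the N2 libraries, built from differences between replicates, gave 0.314 to 0.644. The covariances in the same order were 16.47, 12.3, 18.2, 13.7 and 11.2, against a simulated mean of 8.72 and a range of 5.94 to 14.1, exceeded by pos-1 with gld-3 and by gld-3 with gld-2. All 40 pairs reuse the same difference between the N2 replicates. Their range leaves out how far that difference could vary, so exceeding it was not a test. After centring, gld-3 RNAi and gld-2 RNAi shared 13 genes called shorter, 2 called longer and 1 called in opposite directions. Independent lists would share 0.321 and 0.0461 of the first 2 kinds, and unchanged groups simulated against common N2 libraries shared at most 1 gene in a direction in 40 draws. The first of these leaves out the common N2 libraries and the second leaves out real changes, so part of the excess can come from N2.

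Camera called 58 pairs of a list and a comparison for expression and 22 for tail length with the preset correlation, and 3 and 0 with an estimated one. The RNAi machinery list was called in 1 comparison, pos-1 RNAi against mex-5 RNAi, with 3 of 16 members called higher and 1 lower, 2 and 1 when adjusted over the list alone. Its median was 0.46 (camera adjusted p = 0.0499, adjusted p = 0.15 with an estimated correlation). For expression the stress genes had medians of -0.28 in pos-1 RNAi, 0.22 in gld-3 RNAi, -0.07 in gld-2 RNAi, -0.01 in mex-5 RNAi and 0.04 in mex-6(pk440), with camera adjusted p from 0.43 to 0.95. Ribosomal protein genes had tails with a median difference from N2 of -3.54 nt in pos-1 RNAi, -3.93 nt in gld-3 RNAi, -3.05 nt in gld-2 RNAi, -3.33 nt in mex-5 RNAi and -1.44 nt in mex-6(pk440), with 0 of 66 called in each over all genes. Adjusted over the list alone, 19 were called shorter and 1 longer in gld-3 RNAi, and 0 in the other groups. Camera adjusted p ran from 2.6e-24 in pos-1 RNAi to 0.0018 in mex-6(pk440), and from 0.14 to 0.91 with an estimated correlation.

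Poly(A) site choice was tested in 1519 genes with more than 1 peak. In gld-2 RNAi edgeR called 3 genes (97 at an unadjusted p under 0.05), gap-2, cdc-14 and D1014.2, named because so few passed. In gap-2 the peak on chromosome X at 9514549 to 9514649 had 6 and 0 reads in gld-2 RNAi against 36 and 26 in N2 (adjusted p = 0.0025). With peaks of a mean of at least 20 reads edgeR called 0 of 985 genes in gld-2 RNAi (49 at an unadjusted p under 0.05), where gap-2 and D1014.2 could no longer be tested and cdc-14 did not pass (adjusted p = 0.097), and 1 in mex-5 RNAi. In the other groups edgeR called 0 genes with all peaks, with 40 in pos-1 RNAi, 70 in gld-3 RNAi, 74 in mex-5 RNAi and 22 in mex-6(pk440) at an unadjusted p under 0.05. A log2 change of 2 in 1 peak was planted in simulated data whose spread among the peaks of a gene was set by hand. The shares found there may therefore not hold for these libraries. The edgeR test found 14.5% of 193 changed genes, and a limma test on the log-ratio of each peak to the other peaks of its gene found 88.1%. The latter test, chosen after the data were seen, called 1 gene in gld-2 RNAi (D1014.2), 1 in mex-5 RNAi (E01G4.5) and 0 in the other 3 groups, with 67 in pos-1 RNAi, 102 in gld-3 RNAi and 39 in mex-6(pk440) at an unadjusted p under 0.05. With a replicate block edgeR called 14 genes in mex-5 RNAi, 6 in gld-2 RNAi and 1 in gld-3 RNAi. Leaving out single libraries moved the edgeR counts to between 1 and 4 in gld-2 RNAi, 0 and 2 in mex-5 RNAi, and 0 and 4 in mex-6(pk440).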

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

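The tests of explanations in this part were chosen after the patterns were seen, except that the centring and weighting of neg-1 tails had been planned; the tests of the peaks without a gene were not among the planned comparisons either. Data that the comparisons of genes do not use are the poly(A) peaks assigned to no gene. Of 660 such peaks, 616 had enough reads to be tested with edgeR in a fit over 13082 peaks. Called higher than in N2 (Benjamini-Hochberg, adjusted p under 0.05) were 27 in pos-1 RNAi, 15 in gld-3 RNAi, 46 in gld-2 RNAi, 63 in mex-5 RNAi and 1 in mex-6(pk440). Called lower were 20, 14, 52, 47 and 3, in the same order. The 47, 29, 98 and 110 called in the 4 RNAi groups are smaller shares of their peaks than the 1288, 878, 2777 and 3071 called among all 13082 peaks, so peaks without a gene did not stand out there. In mex-6(pk440) 4 of the 616 were called against 9 of all 13082, a larger share that rests on few calls and was not itself tested. What these peaks belong to was not tested.

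The first pattern weighed is that yolk and adult intestine transcripts and sperm transcripts were higher in N2 and gld-2 RNAi than in the other 4 groups, as list means. In mex-6(pk440) sperm genes were not called lower one by one, and yolk genes were called only when adjusted over the list alone. Adult tissue of one composition, carried over in unequal amounts, would move both lists by the same log2 amount only if all members came from it alone. The yolk mean less the sperm mean spread over the groups by 2.43 (SE of a group mean 0.191) where replicates allow 1.08, and by 1.34 without mex-5 RNAi. In mex-5 RNAi some yolk list members were called higher, while vit-4 stood at 10.1 CPM against 72.3 CPM in N2. Members of that list thus moved apart, so the spread could not count against this explanation. The bacterial food was argued against as the whole cause, since gld-2 RNAi, on the same strain as the other RNAi groups, stood 2.00 above them in the yolk mean (SE 0.325). The food of mex-6(pk440) is not given by the labels, and its deposited columns are named RNAi, so its low values were not used here. Carry-over of adult tissue of one composition stays open. So do carry-over of adult tissues in differing mixtures, embryo stage and the depletions themselves, which were not tested. Both lists hold transcripts of adult tissues, so their moves may not be changes in the embryo.

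The second pattern is that acdh-1 transcripts were lower in the 4 RNAi groups than in N2 and mex-6(pk440). Carry-over of adult tissue alone was argued against, since acdh-1 differed by -2.09 (log2, SE 0.50) in gld-2 RNAi, where the yolk mean was 0.43 above N2. Without gld-2 RNAi replicate 2 the acdh-1 difference was -1.71 and missed the threshold. Food and RNAi changed there too, so a part from carry-over stays open. Among RNAi groups acdh-1 was highest in gld-2 RNAi (14.9 ± 6.76 CPM, SD), as was the yolk mean. It was 5.77 ± 4.75 in pos-1 RNAi, 5.50 ± 2.69 in gld-3 RNAi and 5.85 ± 3.01 in mex-5 RNAi. In mex-6(pk440) acdh-1 was 74.7 ± 26.5 CPM, though the yolk mean there was below N2. Conditions of feeding RNAi shared by the 4 groups remain a candidate explanation, and cannot be told apart from the depletions by these tables. Of 3 other propionate shunt genes, 2 (hphd-1 and hach-1) were lower in all 8 RNAi libraries than in the other 4, while alh-8 was not. Bacterial strain and double-stranded RNA changed together in these groups, and the food of mex-6(pk440), set here beside N2, is not given by the labels.

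The third pattern is that the neg-1 tail was shorter in gld-3 RNAi than in N2 and less so in gld-2 RNAi, a difference between the groups that passed only on the log2 scale. A shift of tail length in whole libraries was argued against. The difference from N2 after centring was -21.2 nt (adjusted p = 0.014, against -18.6 nt and 0.15 as measured). Weighting by reads gave -19.5 nt (SE 3.76 in the unweighted fit), but could not judge few reads behind single values. A weighted mean of 2 libraries stays between their values, and both gld-3 RNAi values lay below both N2 values. Any weights would therefore leave the tail shorter in gld-3 RNAi, so few reads stay open. Whether gld-2 RNAi did less because it left more of its target cannot be told apart, since it left 44.3% of gld-2 but the library with less gld-2 had the longer neg-1 tail. A dependence of neg-1 tails on GLD-3 may be offered as a hypothesis, found and tested on the same 12 libraries. The shortening was not particular to neg-1, since mex-5 and pos-1 tails also passed as shorter in gld-3 RNAi after centring.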

How the results depend on the processing

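Alternatives with mex-6(pk440) as the control, tails centred and scaled, rRNA left out, lists on centred tails, the log-ratio test and the linear model on library medians were chosen after the results were seen; the others were planned. Counts of genes called are given where they moved by more than 1.5 times, and the cause was not tested unless fewer samples or genes explain it by construction. The alternative of at least 5 reads per tail value was void, since no tail value stands under a count of 10.

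For expression, RLE factors and rRNA left out kept every count within 1.5 times, and DESeq2 did so except in mex-6(pk440) (74). With no low-count filter the counts were 1279 in gld-3 RNAi, 172 in mex-6(pk440), 660 in pos-1 RNAi vs gld-3 RNAi and 1649 in gld-3 RNAi vs gld-2 RNAi. With the 4 samples alone, fewer samples by construction, they were 390 in pos-1 RNAi, 313 in gld-3 RNAi, 34 in mex-6(pk440) and 108 in pos-1 RNAi vs gld-3 RNAi. With mex-6(pk440) as the control they were 436 in pos-1 RNAi and 48 in gld-3 RNAi, and mex-6 itself reversed in mex-5 RNAi (1.89), because mex-6 is lower still in that control. Leaving out 1 library, where the lone sample is assumed to vary like the other groups, gave 355 to 843 in pos-1 RNAi, 125 to 729 in gld-3 RNAi, 1184 to 1572 in gld-2 RNAi, 1855 to 2134 in mex-5 RNAi, 1 to 9 in mex-6(pk440), 146 to 321 in pos-1 RNAi vs gld-3 RNAi, 258 to 671 in gld-3 RNAi vs gld-2 RNAi and 931 to 1351 in mex-5 RNAi vs mex-6(pk440). The pos-1 RNAi vs mex-5 RNAi count stayed within 1.5 times in every setting run.

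Tail counts moved more. With at least 50 reads they were 3 in pos-1 RNAi, 3 in gld-3 RNAi, 44 in gld-2 RNAi and 52 in mex-5 RNAi. With weights they were 0 in pos-1 RNAi, 14 in gld-3 RNAi, 20 in gld-2 RNAi and 55 in pos-1 RNAi vs gld-3 RNAi. Centring gave 48 in gld-3 RNAi, 73 in gld-2 RNAi, 94 in mex-5 RNAi, 78 in pos-1 RNAi vs gld-3 RNAi, 147 in pos-1 RNAi vs mex-5 RNAi, 62 in gld-3 RNAi vs gld-2 RNAi and 47 in mex-5 RNAi vs mex-6(pk440). Centring and scaling gave 2, 129, 240, 308 and 1 in the 5 comparisons with N2, in the order pos-1, gld-3, gld-2, mex-5 and mex-6, and 69, 135, 69 and 135 in the other 4. On the log2 scale they were 3 in pos-1 RNAi, 9 in gld-3 RNAi, 60 in gld-2 RNAi, 98 in mex-5 RNAi, 1 in mex-6(pk440), 61 in gld-3 RNAi vs gld-2 RNAi and 29 in mex-5 RNAi vs mex-6(pk440). The 4 samples alone gave 0 in pos-1 RNAi, gld-3 RNAi, mex-5 RNAi and mex-5 RNAi vs mex-6(pk440), 1 in gld-2 RNAi, 12 in pos-1 RNAi vs mex-5 RNAi and 2 in gld-3 RNAi vs gld-2 RNAi. With mex-6(pk440) as the control they were 0 in pos-1 RNAi, 87 in gld-2 RNAi and 4 in mex-5 RNAi. Leaving out 1 library gave 0 to 8 in pos-1 RNAi, 0 to 6 in gld-3 RNAi, 0 to 41 in gld-2 RNAi, 0 to 25 in mex-5 RNAi, 0 to 9 in pos-1 RNAi vs gld-3 RNAi, 0 to 3 in pos-1 RNAi vs mex-5 RNAi and 3 to 15 in gld-3 RNAi vs gld-2 RNAi. In mex-5 RNAi vs mex-6(pk440) it gave 0 for each library left out.

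The replicate block, which assumes that equal replicate numbers share conditions, gave 1206 expression calls in gld-3 RNAi and 44 in mex-6(pk440). For tails it gave 0 in pos-1 RNAi, 2 in gld-3 RNAi, 10 in mex-5 RNAi and 28 in pos-1 RNAi vs mex-5 RNAi, and for site choice 1 in gld-3 RNAi, 6 in gld-2 RNAi and 14 in mex-5 RNAi. The labels do not pair samples across groups. Differences between replicates correlated above 0.1 in 10 of 15 pairs of groups for expression (median 0.28, highest 0.71) and in 5 of 15 for tails. In every group replicate 2 had fewer gene reads and a larger rRNA share than replicate 1. Equal replicate numbers may therefore share conditions, which the main fits leave out.

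Poly(A) site counts were 0 in gld-2 RNAi and 1 in mex-5 RNAi with peaks of a mean of at least 20 reads, and 1 in each with log-ratios. Leaving out 1 library gave 1 to 4 in gld-2 RNAi, 0 to 2 in mex-5 RNAi and 0 to 4 in mex-6(pk440). The neg-1 tail in gld-3 RNAi vs N2 passed when weighted (-19.5 nt), centred (-21.2 nt) or centred and scaled (-19.6 nt), and on the log2 scale. It did not pass as measured, with a replicate block or with the samples of the 2 groups alone. In pos-1 RNAi vs gld-3 RNAi it did not pass on its peak (23.4 nt) or without 1 library (20.3 to 26.6 nt). With an estimated correlation, pairs of lists and comparisons called went from 58 to 3 for expression and from 22 to 0 for tails; centring left 19 of the latter kind.

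Among named genes, 71 of 80 gene and comparison pairs for expression and 8 of 21 for tails kept direction and side of the threshold in every setting run. Over the settings run, 17 of 851 lost the call for expression, and for tails 33 of 232 lost it and 5 gained it.

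Depth limited the gld-2 transcript (15 reads in the lowest library) and the neg-1 peak (25 reads in the lowest), and genes under 10 reads in any library had no tail test.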

Other observations

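Expression calls shared between groups were counted beside the number that independent lists would share; N2 is common to the comparisons, which raises these numbers. In gld-2 RNAi and mex-5 RNAi, 807 genes were higher in both (248 for independent lists) and 385 lower in both (150), with 81 opposite. In pos-1 RNAi and gld-3 RNAi, 184 were higher in both (17.9) and 242 lower in both (28.4), with 27 opposite. In gld-3 RNAi and gld-2 RNAi, 280 were higher in both (54.9) and 101 lower in both (48.2), with 9 opposite. In gld-3 RNAi and mex-5 RNAi, 210 were higher in both (70.2) and 233 lower in both (47.2), with 32 opposite. The pos-1 RNAi and gld-2 RNAi pair went both ways, with 246 higher in both (63.4) but 74 lower in both (90.2, more than observed) and 134 opposite. Pairs with mex-6(pk440) shared at most 2. In pos-1 RNAi and mex-5 RNAi, 195 were higher in both (81) and 244 lower in both (88.2), with 192 opposite, ceh-32 among them. Across genes, Pearson's r between the expression changes of 2 groups ran from 0.113 (pos-1 RNAi and gld-2 RNAi) to 0.647 (gld-3 RNAi and mex-6(pk440)), and none of the 10 exceeded the highest r of 40 simulated pairs of unchanged groups (0.747, mean 0.513). Their covariances ran from 0.124 to 0.806, against a simulated mean of 0.0943 and maximum of 0.157, which that of pos-1 RNAi and gld-2 RNAi did not exceed while the other 9 did. These simulated pairs all reuse the same difference between the N2 replicates, so exceeding them was not a test. Unchanged groups simulated against common N2 libraries shared 0 genes in 40 draws, a number that leaves out real changes.

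Across genes, tail changes and expression changes were weakly related, with Pearson's r from -0.218 (gld-3 RNAi vs gld-2 RNAi) to 0.205 (pos-1 RNAi vs N2). Tails of the oocyte gene egg-1 followed those of cpg-3, at 36.8 ± 1.90 nt in N2 (SD, n = 2), 50.6 ± 0.599 nt in gld-2 RNAi and 27.3 ± 3.69 nt in mex-6(pk440). This gene was chosen after its values were seen.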
